A study of Oryza sativa with 40 samples.

How the data were processed

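Leaves of rice (Oryza sativa) cultivar IR64 were measured by total RNA sequencing, from 61-cycle single-end reads of stranded libraries depleted of ribosomal RNA. Plants grew in hydroponic tanks at 30/25 °C (day/night, called warm). Of 12 tanks, 4 were moved to 40/35 °C (hot), 4 were moved to 25/20 °C (cold) and 4 stayed warm. The middle section of leaves that were full-grown before the move was harvested 0, 2, 6 and 24 h after it, always by day. There are 40 libraries in 10 groups of 4: warm at 0, 2, 6 and 24 h, hot at 2, 6 and 24 h, and cold at 2, 6 and 24 h. The labels do not say which tank gave which library, and replicate numbers were not taken to pair libraries.

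The authors deposited a single table with a log2 value per gene and library, as limma voom writes it: the read count plus 0.5, divided by a scaled library size and given as log2 CPM. Per the labels, the tools before that table were bcl2fastq, FastQC 0.11.2, Subread 1.5.0-p1, SAMtools 1.1-26, bedtools, featureCounts 1.5.0-p1, edgeR 3.4.2 and limma 3.20.1, with genome build IRGSP-1.0. The strand setting of the counting, the filter on low counts and the method of library scaling are not given in the sources used here. Read counts were recovered from the deposited values: in every library, 100% of the values gave a whole number of reads within 0.001. Reads assigned to genes ran from 1830817 (warm 24 h, replicate 3) to 9628451 (warm 24 h, replicate 4), with a median of 5853252. A floor of 3 reads stood for 0.293 to 2.059 CPM, depending on the library. The floors cover counting error only, since reads without molecular identifiers are not independent molecules. The 95% intervals come from the fit and cover the spread between libraries. The table holds 19308 genes, 19284 of them on the 12 chromosomes. Of all genes, 949 are annotated as transposon or retrotransposon proteins. No genome sequence was used here.

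The comparisons, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except where a list or alternative is called added. A single model of the 10 groups was fitted to the deposited log2 values of all genes with limma 3.58.1 in R 4.3.3, with an intensity-dependent prior and robust empirical Bayes estimation. Each hot or cold group was set against the warm group of its own hour. The warm 24 h group was set against warm 0 h. A moderated F test asked for change over the warm hours, and the hot and cold changes at 24 h were tested against those at 2 h as differences. All tests were two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of that comparison, and calls with a fold change of at least 2 were counted too. Changes are log2 differences with the standard error (SE) of the fit, and n = 4 libraries per group throughout. Tables were prepared and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

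The 26 gene lists combine identifiers written beforehand with patterns on the product names in the table. They cover heat stress transcription factors, small heat shock proteins, HSP70, HSP90 and HSP101 chaperones, chaperonins and DnaJ co-chaperones, other heat-induced genes, the unfolded protein response of the endoplasmic reticulum, DREB1 and cold signalling factors, and the circadian clock. They further cover light harvesting and photosystem proteins, the Calvin-Benson cycle, photorespiration, respiratory chain complexes, the alternative respiratory pathway, starch and sucrose metabolism, antioxidant enzymes, lipid desaturases, and abscisic acid metabolism and response. The remaining lists hold flavonoid and phenylpropanoid enzymes, cytosolic ribosomal proteins, chloroplast and mitochondrial ribosomal proteins, ribosome biogenesis, proteasome subunits, spliceosome and splicing factors, dividing cell markers, vascular and secondary wall markers, and guard cell markers. Of 187 identifiers in the lists, 158 were measured, and 6 were left out because the product name in the table did not match. The table pairs identifiers with product names but not with gene symbols, so symbols printed here come from the lists and not from the data. Lists were tested with camera (limma) at its preset correlation of 0.01, adjusted over the 25 lists of at least 3 measured members in each comparison. The members that passed were counted over all genes and adjusted over the list alone. Another 4 lists were added after the data were seen.

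Genes named in the text are the 3 largest rises and 3 largest falls of each shift among genes that passed, that had all 4 treated libraries beyond all 4 warm libraries, a mean log2 value of at least 2 and an informative product name. The 2 members of each list with the largest change among its passing members, at the hour where it was largest, were named as well. HSP101, HSFA2C, DREB1A, DREB1B, AOX1A, RCA, LHY and PRR1 were always named, and the 2 clock genes with the smallest p stand for the warm time course. Genes called further members in the report were chosen after their values were seen.

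The alternatives were filters at a mean log2 value of 1 and of 3, libraries shifted to one median, quantile normalization, the log2 of CPM plus 1, no trend and no robust estimation, sample weights, and a fit of only the groups compared. Others were a replicate block, the sequencing lane as a term, both together, an adjusted p under 0.01, voom weights on recovered reads, and each library of the groups compared left out in turn. For counts of 0, leaving out libraries of the other groups was looked at too. For the lists, camera with an estimated correlation and fry were run. Fits without warm 0 h replicate 1, without hot 24 h replicate 1 and without both were added after these libraries were seen to stand apart. The procedure was tested on simulated data with the recovered depths: log2 changes of 1, 2 and 3 were called for 37.3%, 79.1% and 92.4% of the simulated genes, and 4.8% of the calls were false. That simulation changed 67, 67 and 66 of 19308 genes and drew genes independently. It had no lane effect and no library that stood apart, so these shares may not carry over to the real data.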

Results

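The data are 40 RNA-seq libraries from the middle of rice leaves, taken 0, 2, 6 and 24 h after plants were moved from 30/25 °C to 40/35 °C or to 25/20 °C, or were left at 30/25 °C. Each of the 10 groups has 4 libraries. Because the series concerns how existing leaves adjust to a new temperature, every shifted group was compared with warm leaves of the same hour. The 24 h samples fall at the same time of day as the 0 h samples. Total reads per library lay between 1830817 and 9628451. The most abundant transcripts were those of leaf photosynthesis: Rubisco activase (RCA, LOC_Os11g47970, annotated as an AAA-type ATPase) took 2.617% of reads on average, a photosynthetic reaction center protein (LOC_Os04g16770) 1.705%, and a Rubisco small chain (LOC_Os12g19381) 1.504%.

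Libraries correlated with their group mates at a mean r of 0.9346 to 0.97 in 8 of the groups. Warm 0 h replicate 1 stood apart at 0.8597, against 0.9223 to 0.9286 for its mates, and the hot 24 h libraries spread from 0.8944 (replicate 1) to 0.9319. The library names give 4 sequencing lanes, which follow temperature in large part. Warm libraries ran on lanes 1 and 2, hot libraries on lanes 2 and 3, and cold libraries on lanes 3 and 4, so warm and cold never shared a lane.

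After 2 h of heat, some genes of abscisic acid (ABA) signalling, of the circadian clock and of starch metabolism were lower than in warm leaves. Some genes for chaperones of the endoplasmic reticulum and for cytosolic ribosomal proteins were higher. None of these list calls passed with an estimated correlation, while all of them passed with fry. The fry adjusted p was 0.000433 for the ABA, clock and starch lists. It was 0.000653 for the endoplasmic reticulum list and 0.0271 for cytosolic ribosomal proteins. Of 14 measured ABA genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with a median log2 change of -1.56. They include NCED4 (LOC_Os07g05940, chromosome 7, 2870686 to 2872832), an enzyme that makes the ABA precursor, at -5.69 ± 1.18 (SE, n = 4, adjusted p = 0.00252). Its geometric mean went from 11.2 CPM in warm leaves to 0.217 CPM in hot ones, which is below the floor of 3 reads, so the size of its change depends on the offset of 0.5. The NAC transcription factor SNAC1 (LOC_Os03g60080) was at -2.86 ± 0.71 (adjusted p = 0.0114), a call lost with lane as a term. Further members that fell are the phosphatases PP2C30 (LOC_Os03g16170, -2.40) and PP2C50 (LOC_Os05g46040, -1.50), the dehydrin LIP9 (LOC_Os02g44870, -2.20) and BZIP23 (LOC_Os02g52780, -1.53). The list as a whole was lower than other genes (camera adjusted p = 5.7e-07, and adjusted p = 0.0986 with an estimated correlation). At 6 h of heat 0 members passed by either adjustment (median -0.235, camera adjusted p = 0.823). At 6 h of cold 0 passed too, with 3 of 14 fitted changes above 0. The median there was -0.415 (camera adjusted p = 0.0126, and adjusted p = 0.429 with an estimated correlation). Some markers of other cell types lay about as low as the ABA list at 2 h of heat. The 43 dividing cell markers did not (median -0.292, camera adjusted p = 0.116). Vascular and secondary wall markers were at -1.81, with 1 of 6 fitted changes above 0 (0 members by either adjustment, camera adjusted p = 0.105). The single measured guard cell gene, the anion channel SLAC1, was at -1.48 (0 falls over all genes, 1 adjusted over the list alone).

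Of 14 measured clock genes, 7 fell and 0 rose at 2 h (10 and 0 adjusted over the list alone), with a median of -0.886 (camera adjusted p = 8.54e-06, and adjusted p = 0.0986 with an estimated correlation). The morning-phased LHY (LOC_Os08g06110, a MYB factor on chromosome 8, 3365730 to 3373434) was at -1.13 ± 0.22 (adjusted p = 0.0017), and the evening-phased PRR1 (LOC_Os02g40510) at -1.83 ± 0.58 (adjusted p = 0.0447). FKF1 (LOC_Os11g34460) was at -2.14 ± 0.66 and LUX (LOC_Os01g74020) at -1.95 ± 0.62, so morning and evening genes were lower at the same time. LUX had a mean of 0.448 CPM in hot leaves, near the floor of 3 reads. It was at -0.83 with the log2 of CPM plus 1. Its call was lost there, with only the groups compared and with voom weights. The further member PRR95 (LOC_Os09g36220) was at -1.69 (adjusted p = 0.00153). The calls of FKF1, LUX and PRR1 were lost without any single library of the 8 other than hot 2 h replicate 2, with lane as a term and with no trend and no robust estimation, and PRR1 also with the replicate block. LHY lost its call only with quantile normalization and with lane as a term, alone or with the block.

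Of 6 genes in the list of the endoplasmic reticulum unfolded protein response, 5 rose at 2 h (5 adjusted over the list alone, median 0.854, camera adjusted p = 0.000106, and adjusted p = 0.137 with an estimated correlation). The list holds no BiP chaperone: BIP1 (LOC_Os02g02410) was measured but left out because its product name did not match, and BIP3, BIP4 and BIP5 were not measured. The protein disulfide isomerase PDIL2-3 (LOC_Os09g27830, chromosome 9, 16930987 to 16935970) rose by 1.17 ± 0.21 (adjusted p = 0.000718). The chaperone GRP94 (LOC_Os06g50300) rose by 0.97 ± 0.24 (adjusted p = 0.0106), a call lost without hot 2 h replicate 4 and with lane as a term. The further members calreticulin CRT1 (LOC_Os07g14270, 0.92), CNX (LOC_Os04g32950, 0.79) and PDIL1-1 (LOC_Os11g09280, 0.77) rose too, and the factor BZIP50 (LOC_Os06g41770) was at -0.20 and did not pass. Of 119 cytosolic ribosomal protein genes, 24 rose and 0 fell (72 and 0 adjusted over the list alone). In all, 115 had a fitted change above 0. Their median was 0.784 (camera adjusted p = 2.59e-21, and adjusted p = 0.329 with an estimated correlation). Among them, 40S S9-1 (LOC_Os03g26229) rose by 1.79 ± 0.36 and 60S L37a (LOC_Os05g48320) by 1.52 ± 0.33. Reads of such near-identical paralogues can be shared between loci. In cold leaves at 2 h, set against the same warm libraries, 104 of these 119 genes also had a fitted change above 0. There 0 members passed by either adjustment (median 0.236, camera adjusted p = 6.71e-06, and adjusted p = 0.853 with an estimated correlation).

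More genes of starch and sucrose metabolism fell than rose at both hours, and the list call did not pass with an estimated correlation at either. With fry the list passed at both (adjusted p = 0.000433 at 2 h and 7.97e-05 at 6 h). At 2 h, 11 of 48 members fell and 2 rose (14 and 4 adjusted over the list alone, median -0.329, camera adjusted p = 0.00102, and adjusted p = 0.0986 with an estimated correlation). At 6 h, 9 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.246, camera adjusted p = 0.00107, and adjusted p = 0.268 with an estimated correlation). Markers of other cell types lay lower too at 6 h. The vascular and secondary wall markers had a median of -1.11, with 0 of 6 fitted changes above 0 (0 members by either adjustment, camera adjusted p = 0.248), and SLAC1 was at -1.51 (0 falls over all genes, 1 adjusted over the list alone). A beta-amylase (LOC_Os07g35880), a starch-degrading enzyme, was at -2.60 ± 0.51 at 6 h (adjusted p = 0.00105), from 71.9 to 11.9 CPM. A starch synthase (LOC_Os07g22930, chromosome 7, 12916277 to 12921186) was at -2.39 ± 0.32 (adjusted p = 7.49e-06), from 487 to 93.2 CPM, and passed in all 15 alternatives and all 8 fits without a single library. As a further member, a sucrose-phosphate synthase (LOC_Os01g69030) had the smallest adjusted p of any shift, 2.18e-10, at -2.34. The members that fell thus act in both synthesis and breakdown of starch, and the 2 risers at 2 h were a sucrose synthase (LOC_Os03g22120, 1.53) and an invertase (LOC_Os11g07440, 1.45).

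Genes of the classical heat shock response were mostly not among those that changed at 2 h. Of 20 small heat shock protein genes, 0 rose and 1 fell (the same numbers adjusted over the list alone), with a median of -0.389 (camera adjusted p = 0.326). The 1 that fell (LOC_Os03g06170) was at -0.79 ± 0.22, a call lost with lane as a term and without warm 2 h replicate 3 or hot 2 h replicates 1, 3 or 4. Of 16 HSP70, HSP90 and HSP101 genes, 0 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.161, camera adjusted p = 0.875). That member, an HSP70 (LOC_Os03g16860), was at -1.67 ± 0.34 (adjusted p = 0.00206). HSP101 (LOC_Os05g44340), the disaggregating chaperone needed for thermotolerance, was at 0.42 (95% interval -0.19 to 1.04) and did not pass. Of 19 heat stress transcription factors, 2 fell and 0 rose (2 and 0 adjusted over the list alone, median -0.705, camera adjusted p = 0.00131, and adjusted p = 0.202 with an estimated correlation). HSFC2A (LOC_Os02g13800) was at -2.40 ± 0.56, not passing with lane as a term.

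Outside the lists, the largest rises at 2 h were a universal stress protein (LOC_Os05g28740, 3.22 ± 0.89, adjusted p = 0.0216), the Bowman-Birk trypsin inhibitor BBTI13 (LOC_Os03g60840, 2.83 ± 0.58, adjusted p = 0.00231) and a hAT dimerisation domain protein (LOC_Os01g12280, 2.51 ± 0.42, adjusted p = 0.000401). The universal stress protein lost its call with lane as a term, with only the groups compared, and without warm 2 h replicate 1, hot 2 h replicate 3 or hot 2 h replicate 4. The largest fall was that of a glycosyl hydrolase of family 16 (LOC_Os06g48200, chromosome 6, 29156425 to 29157883), a cell wall enzyme family, at -5.32 ± 0.90 (adjusted p = 0.000401). It went from 95.2 to 2.37 CPM and passed in every alternative and without each single library. Next came a gene annotated as a retrotransposon protein (LOC_Os08g39810, -3.62 ± 0.93, adjusted p = 0.013, from 40.6 to 3.29 CPM), a call lost without hot 2 h replicate 4. An early light-induced protein (LOC_Os07g08150), from a family that protects against excess light, was at -3.51 ± 1.05 at 2 h and -4.19 ± 1.05 at 6 h. Its 2 h call was lost without warm 2 h replicates 1, 3 or 4 or hot 2 h replicates 3 or 4, and its 6 h call with lane as a term and with voom weights.

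**Figure D1:**
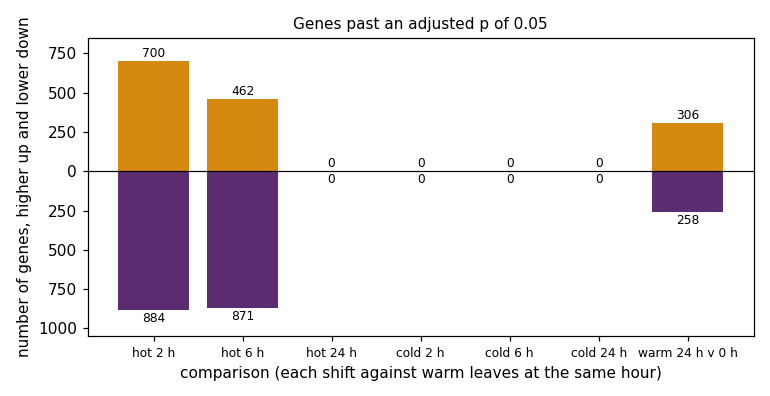
Number of genes (y axis) with an adjusted p under 0.05 in limma for each comparison (x axis), with higher genes drawn up and lower genes down. Calls were made at 2 h and 6 h of heat (700 and 462 higher, 884 and 871 lower) and between the warm 0 h and 24 h groups, and 0 in the other shifts.

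In all, 1584 of 19308 genes changed at 2 h of heat (8.2%), 700 higher and 884 lower, and 905 of them by at least 2-fold. With lane as a term 553 genes passed, 538 of them among the 1584. In lane 2, which held 1 warm and 2 hot libraries of this hour, the 739 genes called between lanes 1 and 3 had a median change of 0.905 in the direction of the call, against the 1.549 they were called on. Without warm 2 h replicates 1, 3 and 4 in turn the count was 910, 866 and 849, and without hot 2 h replicates 1, 3 and 4 it was 1008, 762 and 582. Without both libraries that stood apart it was 2705.

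After 6 h of heat, LHY was still lower. It was at -1.76 ± 0.22 (adjusted p = 3.33e-06) and passed in all 15 alternatives and all 8 fits without a single library, although the clock list had only this 1 fall (1 adjusted over the list alone, median -0.275, camera adjusted p = 0.0292, lost without warm 6 h replicate 2, and adjusted p = 0.627 with an estimated correlation). The glycine dehydrogenase of photorespiration GDC-P (LOC_Os01g51410, chromosome 1, 29560350 to 29567065) was at -1.80 ± 0.30 (adjusted p = 0.000129), from 5320 to 1530 CPM. Of 56 chloroplast and mitochondrial ribosomal protein genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.368, camera adjusted p = 1.49e-05, and adjusted p = 0.268 with an estimated correlation). The plastid 50S L21 (LOC_Os02g15900) rose by 1.39 ± 0.25 (adjusted p = 0.000457). Of 72 light harvesting and photosystem genes, 3 rose and 1 fell (0 and 0 adjusted over the list alone, median 0.481, camera adjusted p = 2.06e-05, and adjusted p = 0.649 with an estimated correlation). Besides nuclear-type genes, that list holds genes of chloroplast type at nuclear loci, to which reads of chloroplast transcripts can align. The further member PSBO (LOC_Os01g31690), of the oxygen-evolving complex, rose by 0.93. The 1 that fell was the photoprotection protein PSBS1 (LOC_Os01g64960), at -1.66 ± 0.51 (adjusted p = 0.0413). Its call was lost with libraries shifted to one median, no trend and no robust estimation, the replicate block and lane as a term, and without any single library of the 8 other than warm 6 h replicate 4.

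Cytosolic ribosomal proteins had a median of 0.41 at 6 h, with 1 rise and 0 falls (0 and 0 adjusted over the list alone, camera adjusted p = 4.15e-09, and adjusted p = 0.649 with an estimated correlation). That 1 member (LOC_Os12g34128, 0.84) is annotated as a mitochondrial L16. In the endoplasmic reticulum list 2 genes rose (5 adjusted over the list alone, median 0.514, camera adjusted p = 0.000572, and adjusted p = 0.268 with an estimated correlation), PDIL2-3 by 0.83 and GRP94 by 0.95. Of 43 dividing cell markers, 4 fell and 0 rose (9 and 1 adjusted over the list alone, median -0.475, camera adjusted p = 0.00195, lost without warm 6 h replicate 3 and with lane as a term, and adjusted p = 0.649 with an estimated correlation). HSP70, HSP90 and HSP101 chaperones had 0 passing members, also adjusted over the list alone, and a median of 0.365. Their camera call (adjusted p = 0.0223, and adjusted p = 0.649 with an estimated correlation) was lost without warm 6 h replicate 2 or hot 6 h replicate 2 and with lane as a term.

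Among heat shock genes at 6 h, the small heat shock protein HSP18.6 (LOC_Os06g14240) rose by 2.53 ± 0.67 (adjusted p = 0.0153), from 1.53 to 8.81 CPM. Its call was lost with lane as a term, with voom weights, and without warm 6 h replicates 1 or 2 or hot 6 h replicate 2. The list had 1 rise and 0 falls (2 and 0 adjusted over the list alone), with a median of -0.071 that was 0.009 with quantile normalization, a mean of 0.317 and a camera direction up (adjusted p = 0.612). HSP101 (LOC_Os05g44340) was at 0.64 (95% interval 0.02 to 1.25, adjusted p = 0.227) and did not pass. Among heat stress transcription factors, HSFC1A (LOC_Os01g43590) fell, at -2.79 ± 0.47 (adjusted p = 0.000187, and -1.26 with the log2 of CPM plus 1). Its mean in hot leaves was 0.29 CPM, below the floor of 3 reads, so the size of its change depends on the offset. The further member HSFA2D (LOC_Os03g06630) rose by 1.13 (list median -0.015, camera adjusted p = 0.854). HSA32 (LOC_Os06g46900), a protein tied to lasting thermotolerance, rose by 1.68 ± 0.51 (adjusted p = 0.0378), a call lost without warm 6 h replicates 1 or 3 or hot 6 h replicates 1, 3 or 4, with lane as a term, with the log2 of CPM plus 1, with only the groups compared and with voom weights. Its mean in warm leaves was 0.341 CPM, about the floor of 3 reads, so the size of its change depends on the offset (0.61 with the log2 of CPM plus 1).

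Outside the lists at 6 h, a multidrug resistance-associated protein (LOC_Os01g67580), a kind of ABC transporter, rose by 3.89 ± 0.45 (adjusted p = 7.97e-07), an aspartic proteinase (LOC_Os12g39360) by 2.82 ± 0.54 and a chloride channel (LOC_Os12g25200) by 2.62 ± 0.46. A major facilitator transporter (LOC_Os01g36720) was at -4.36 ± 0.69 and a SOUL heme-binding protein (LOC_Os01g63210) at -4.14 ± 0.43 (adjusted p = 9.55e-08). LOC_Os01g36720 had a mean of 0.341 CPM in hot leaves, at the floor of 3 reads, so the size of its change depends on the offset (-2.51 with the log2 of CPM plus 1). The aspartic proteinase lost its call with lane as a term.

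In all, 1333 genes changed at 6 h of heat (6.9%), 462 higher and 871 lower, and 749 by at least 2-fold. Of the genes changed at 2 h and 6 h, 466 were the same and moved the same way (164 higher and 302 lower, against 16.7 and 39.9 if the lists were independent), and 1 moved the opposite way. Both comparisons have their own warm controls, but they share 1 fit and its estimate of the spread. At both hours warm libraries ran on lanes 1 and 2 and hot libraries on lanes 2 and 3. The libraries may also share tanks, so the numbers for independent lists are not a chance value for this overlap. With lane as a term 267 genes passed at 6 h, and within lane 2, with 2 warm libraries and 1 hot library, the 445 genes called between lanes 1 and 3 had a median change of 1.015 against 1.464. The count was 658 without warm 6 h replicate 1, 788 without hot 6 h replicate 2, 846 without hot 6 h replicate 4 and 2110 without both libraries that stood apart.

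**Figure D2:**
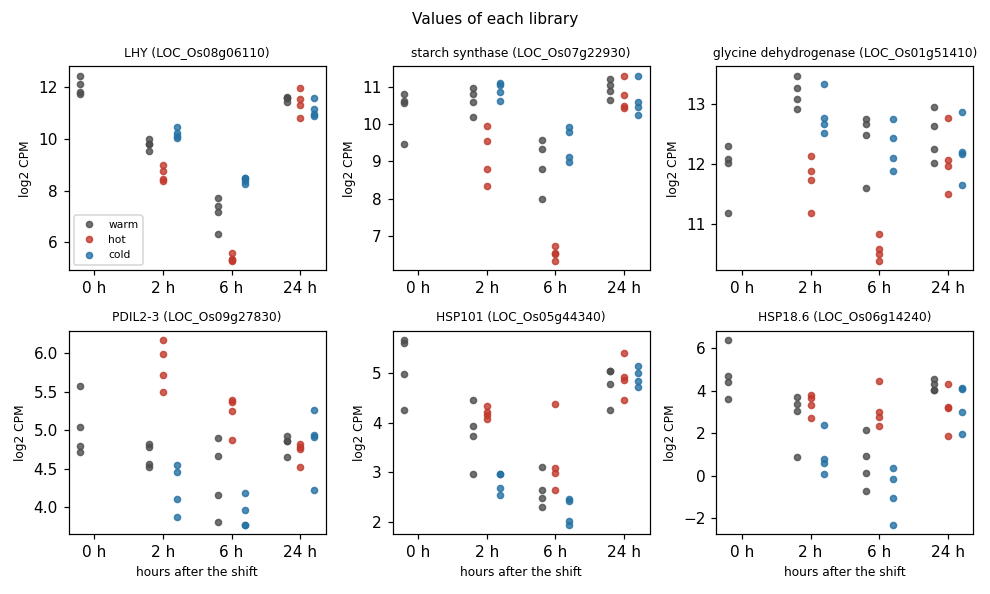
Log2 CPM (y axis) of each library by hour (x axis) and temperature (colour) for 6 genes, with 1 point per library and 4 per group. In hot leaves LHY lay at 8.64 at 2 h and 5.39 at 6 h on average, below the 9.77 and 7.15 of warm leaves, and PDIL2-3 at 5.84 lay above the 4.67 of warm leaves at 2 h.

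After 24 h of heat, limma called 0 genes, with 1206 at an unadjusted p under 0.05 where 965 are expected without change, and 0 with voom weights and 8 with sample weights. LHY was at -0.14, PDIL2-3 at -0.10 and the glycosyl hydrolase LOC_Os06g48200 at 1.29, and none of them passed. The genes changed at 2 h had a median change of 0.045 at 24 h in their earlier direction, against 0.587 at 6 h and 1.09 at 2 h. Only the dividing cell markers had a list call (0 members over all genes, 2 falls adjusted over the list alone, median -0.269, camera adjusted p = 0.00221, lost without hot 24 h replicates 3 or 4 and with lane as a term, and adjusted p = 0.963 with an estimated correlation). The test of the 24 h change against the 2 h change itself passed for 161 genes. Since that difference contains the 2 h change, its sign is not a separate finding. Among them are LOC_Os06g48200 (6.61 ± 1.27, adjusted p = 0.0095), NCED4 (6.57 ± 1.67, adjusted p = 0.0472), PDIL2-3 (-1.27 ± 0.30, adjusted p = 0.0293) and the galactinol synthase GOLS1 (LOC_Os03g20120, annotated as a glycosyl transferase of family 8, 3.76 ± 0.79, adjusted p = 0.0172), whose product leads to raffinose sugars. The count of 161 was 86, 103 and 69 without warm 2 h replicates 1, 3 and 4, 78 and 31 without warm 24 h replicates 1 and 2, 282, 79 and 33 without hot 2 h replicates 2, 3 and 4, and 90 and 711 without hot 24 h replicates 1 and 2. It was 374 with lane as a term.

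In cold leaves the smallest adjusted p belonged to LHY at 6 h, which lay above warm leaves by 1.24 (95% interval 0.79 to 1.69, and adjusted p = 0.0591), opposite to its change in the heat, and did not pass. Its adjusted p ran from 0.00196 to 1 over the alternatives, 6 of 15 of which it passed, and it was 0.00897 without warm 6 h replicate 1. Among the lists at 6 h, all 14 clock genes had fitted changes above 0 (0 rises over all genes, 2 adjusted over the list alone, median 0.266, camera adjusted p = 4.7e-05, lost with lane as a term, and adjusted p = 0.279 with an estimated correlation), as had all 6 lipid desaturases (0 and 0, median 0.675, camera adjusted p = 0.0126, lost without warm 6 h replicate 4, and adjusted p = 0.429 with an estimated correlation), enzymes that make membrane lipids less saturated. Small heat shock proteins were lower at 2 h: 0 members passed by either adjustment, 2 of 20 had a fitted change above 0, and the median was -0.625 (camera adjusted p = 0.000344, and adjusted p = 0.547 with an estimated correlation). HSP101 was at -0.98 at 2 h (95% interval -1.59 to -0.37, and adjusted p = 0.529). The clock list was already higher at 2 h of cold, with 10 of 14 fitted changes above 0. There 0 members passed by either adjustment (median 0.279, camera adjusted p = 0.0253, and adjusted p = 0.853 with an estimated correlation).

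At 24 h of cold, 110 of 119 cytosolic ribosomal protein genes had fitted changes above 0 (0 rises over all genes, 1 adjusted over the list alone, median 0.487, camera adjusted p = 2.27e-18, and adjusted p = 0.476 with an estimated correlation). Light harvesting and photosystem genes, which mix nuclear-type genes with chloroplast-type genes at nuclear loci, had a median of -0.42 (0 falls by either adjustment, camera adjusted p = 1.36e-09, and adjusted p = 0.476 with an estimated correlation). Ribosome biogenesis was at 0.42 (camera adjusted p = 0.000374, lost with lane as a term, and adjusted p = 0.476 with an estimated correlation). The 6 vascular and secondary wall markers were at -1.70 (camera adjusted p = 0.00829, lost with lane as a term and without warm 24 h replicate 3 or cold 24 h replicate 3, and adjusted p = 0.476 with an estimated correlation). In both lists 0 members passed by either adjustment. Dividing cell markers had a median of -0.349 (0 members by either adjustment, camera adjusted p = 0.00201, lost with lane as a term, and adjusted p = 0.497 with an estimated correlation). At 6 h of cold they were at -0.257 (0 members by either adjustment, camera adjusted p = 0.0126, lost with lane as a term and without warm 6 h replicate 3 or cold 6 h replicate 3, and adjusted p = 0.661 with an estimated correlation). In all, 3, 10 and 11 of the lists had a camera call at 2, 6 and 24 h of cold, and 0 had one with an estimated correlation.

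No single gene passed in the cold: limma called 0 genes at 2, 6 and 24 h, with 1251, 869 and 1457 at an unadjusted p under 0.05 where 965 are expected, and 4, 2 and 0 with voom weights. With sample weights the counts were 4, 73 and 136. The count at 6 h was 1 without warm 6 h replicate 1 and 1 without warm 6 h replicate 4, and at 24 h it was 1 without warm 24 h replicate 2. Libraries of other groups mattered as well. The count at 2 h was 1 without warm 0 h replicate 1 and 1 without warm 0 h replicate 4. At 6 h it was 1 (LHY) without warm 0 h replicate 1, hot 24 h replicate 2, hot 24 h replicate 4 or cold 24 h replicate 1. The cold change at 24 h against that at 2 h passed for 0 genes (987 at an unadjusted p under 0.05). Because warm and cold shared no lane, temperature and lane cannot be told apart within a lane for these groups. A fit with lane as a term links them only by way of the hot libraries on lanes 2 and 3. A cold call lost with that term therefore does not decide between temperature and lane.

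**Figure D3:**
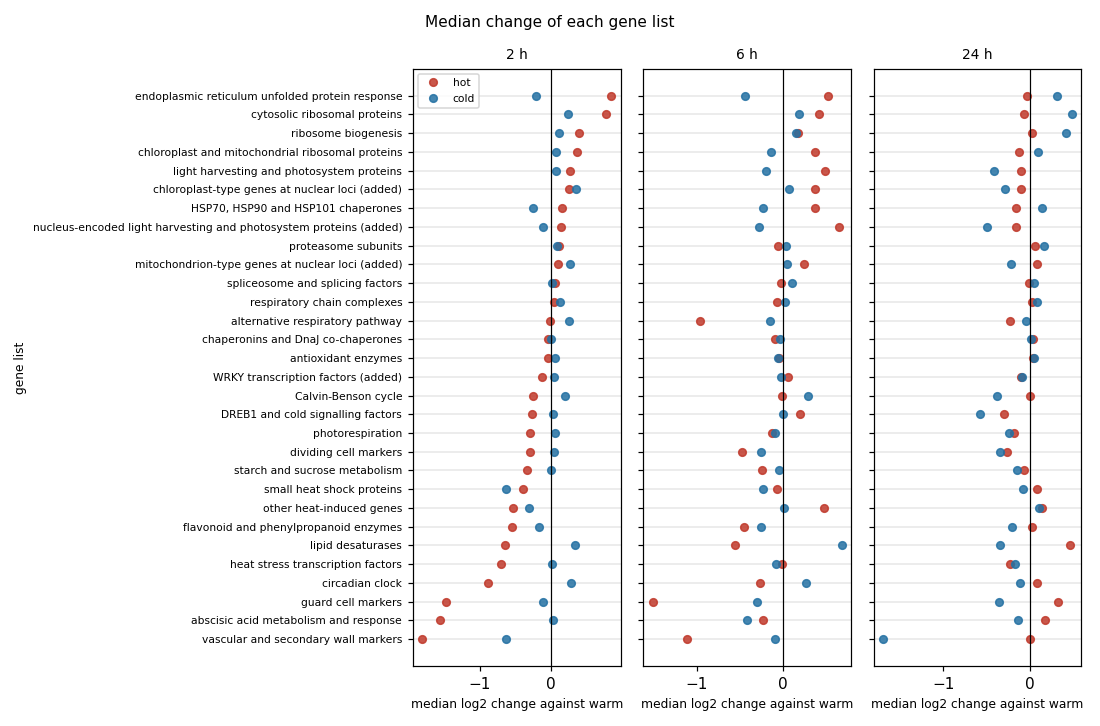
Median log2 change against warm leaves (x axis) of each gene list (y axis) in hot and cold leaves at 2, 6 and 24 h, with 1 point per list and shift. At 2 h of heat the ABA and clock lists lay at -1.56 and -0.886 and the endoplasmic reticulum and cytosolic ribosomal lists at 0.854 and 0.784.

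Whether heat and cold moved the same genes in opposite directions was asked by counting genes called in both. Since limma called 0 genes in the cold at each hour, that count could only be 0 in limma, so it does not answer the question. With voom weights it was 2, 1 and 0 at 2, 6 and 24 h for opposite directions. Across genes, which are not independent replicates, the correlation of the hot and cold changes was 0.096 at 2 h, 0.277 at 6 h and 0.43 at 24 h. Simulated unchanged groups against the same warm controls gave 0.495, 0.503 and 0.499. With the warm libraries split between the comparisons the mean correlation was -0.123 at 2 h (-0.204 to -0.036 over 6 splits), 0.011 at 6 h and 0.01 at 24 h. The 6 h opposite count was 1 without warm 6 h replicate 1.

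Without any shift, 8626 genes (44.7%) changed over the warm hours. LHY had a mean of 12.01 ± 0.32 log2 CPM (SD, n = 4) at 0 h, 9.77 ± 0.20 at 2 h, 7.15 ± 0.59 at 6 h and 11.53 ± 0.10 at 24 h (adjusted p = 1.03e-18). The evening gene LUX ran the other way, at -2.37, 0.79, 7.06 and -1.92 (adjusted p = 8.43e-15). HSP101 also declined by day, from 5.12 ± 0.66 at 0 h to 2.64 ± 0.34 at 6 h, and was at 4.77 ± 0.37 at 24 h. Between the warm 0 h and 24 h groups, taken at the same time of day, 564 genes changed, 306 higher and 258 lower at 24 h, 371 of them by at least 2-fold. As further members, the beta-amylase LOC_Os07g35880 rose by 1.93 and the plastid ribosomal protein LOC_Os03g63950 fell, at -2.75. That count leaned on the 0 h libraries: it was 42 without warm 0 h replicate 1, 1507, 903 and 900 without replicates 2, 3 and 4, 130, 161 and 233 without warm 24 h replicates 1, 3 and 4, and 1 when only these groups were fitted.

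In warm 24 h against 0 h leaves, cytosolic ribosomal proteins were higher (0 rises by either adjustment, median 0.603, camera adjusted p = 2.67e-11, and adjusted p = 0.9 with an estimated correlation) and light harvesting and photosystem genes lower (0 falls by either adjustment, median -0.403, camera adjusted p = 8.4e-05, and adjusted p = 0.9 with an estimated correlation). The vascular and secondary wall markers had a median of 1.74 there (0 rises by either adjustment, camera adjusted p = 0.317). List tests of this comparison were not rerun without single libraries, although its gene count was 42 without warm 0 h replicate 1. The photosystem list again includes chloroplast-type genes at nuclear loci.

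The genes named in advance that did not pass at any hour of heat or cold were HSP101, HSFA2C, DREB1A, DREB1B, AOX1A and RCA. The heat stress factor HSFA2C (LOC_Os10g28340) was at -0.71, 0.28 and -0.50 after 2, 6 and 24 h of heat. The cold-responsive DREB1A (LOC_Os09g35030) was at 1.03, 0.78 and -1.46 in the cold and DREB1B (LOC_Os09g35010) at 1.59, 0.36 and -0.74, with 95% intervals that at 2 h ran from -1.50 to 3.56 and from -1.53 to 4.71. RCA was at -0.54, -0.32 and -0.52 in the heat and -0.03, 0.59 and -0.59 in the cold. AOX1A (LOC_Os04g51150), which the table annotates as a transposon protein, was at 0.62 at its largest, after 24 h of cold.

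At 2 h of heat, flavonoid and phenylpropanoid enzymes had 2 rises and 4 falls among 38 (2 and 5 adjusted over the list alone, median -0.554, camera adjusted p = 0.0178, lost without warm 2 h replicate 3 or hot 2 h replicate 3, and adjusted p = 0.282 with an estimated correlation). Lipid desaturases had 1 fall among 6 (3 adjusted over the list alone, median -0.642, camera adjusted p = 0.0471, and adjusted p = 0.543 with an estimated correlation), an omega-3 desaturase (LOC_Os07g49310) at -2.15 ± 0.68. The list call was lost with each other scaling, the block, lane as a term, and without warm 2 h replicates 2, 3 or 4 or hot 2 h replicates 3 or 4, and that gene's call without any single library other than hot 2 h replicate 2. Ribosome biogenesis had 0 rises by either adjustment among 20 (median 0.399, camera adjusted p = 0.00951, and adjusted p = 0.55 with an estimated correlation), and the organelle ribosomal list 2 rises (0 adjusted over the list alone, median 0.364, camera adjusted p = 0.0178, lost without warm 2 h replicate 3 or hot 2 h replicate 3, and adjusted p = 0.543 with an estimated correlation). The plastid LOC_Os03g63950 rose by 2.07 ± 0.58, a call lost with lane as a term and without warm 2 h replicates 1 or 4 or hot 2 h replicates 1, 3 or 4. Photorespiration had 2 falls among 12 (2 adjusted over the list alone, camera adjusted p = 0.16), GDC-P at -1.45 and LOC_Os06g40940, also a glycine dehydrogenase, at -0.95 (lost without hot 2 h replicate 4). The Calvin-Benson list had 1 fall among 14 (1 adjusted over the list alone, camera adjusted p = 0.105), the fructose-1,6-bisphosphatase cpFBPase (LOC_Os03g16050) at -0.78 ± 0.24. Its call was lost with quantile normalization, lane as a term, and without any single library other than hot 2 h replicates 1 and 2. Light harvesting and photosystem genes had 1 fall among 72 (0 adjusted over the list alone, camera adjusted p = 0.144), PSB28 (LOC_Os01g71190) at -1.49 ± 0.45, lost with lane as a term and without warm 2 h replicates 1, 3 or 4 or hot 2 h replicates 3 or 4. Other heat-induced genes had 1 fall among 8 (2 adjusted over the list alone, camera adjusted p = 0.133), GOLS1 at -2.09 ± 0.56 (lost with lane as a term and without warm 2 h replicates 1 or 3 or hot 2 h replicates 3 or 4). DREB1 and cold signalling factors had 1 fall among 6 (1 adjusted over the list alone, camera adjusted p = 0.16), ICE2 (LOC_Os01g70310) at -1.16 ± 0.24.

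The other lists had no camera call at 2 h of heat. Chaperonins and DnaJ co-chaperones had 4 rises and 3 falls among 95 (the same adjusted over the list alone, camera adjusted p = 0.796). A chaperonin (LOC_Os09g26730) rose by 1.49 ± 0.45, a call lost with lane as a term and without any single library other than warm 2 h replicate 1 and hot 2 h replicate 2. Antioxidant enzymes had 1 fall among 31 (1 adjusted over the list alone, camera adjusted p = 0.958), and respiratory chain complexes 1 rise and 1 fall among 32 (the same adjusted over the list alone, camera adjusted p = 0.661). Spliceosome and splicing factors had 2 falls among 44 (1 adjusted over the list alone, camera adjusted p = 0.488), among them pre-mRNA-processing factor 6 (LOC_Os01g15860, -0.75 ± 0.19), lost with lane as a term and without warm 2 h replicate 4 or hot 2 h replicate 4. Proteasome subunits had 0 passing members among 24 by either adjustment (camera adjusted p = 0.0794), and the alternative respiratory pathway 0 among 3 (1 fall adjusted over the list alone, camera adjusted p = 0.51). The latter list holds no alternative oxidase: AOX1A, AOX1B, AOX1C and UCP1 were left out because their product names did not match, and AOX1D was not measured. Of the marker lists for other cell types, dividing cell markers had 1 rise and 2 falls among 43 (1 and 4 adjusted over the list alone, camera adjusted p = 0.116). The histone gene LOC_Os09g39730 was at -3.05 ± 0.65 (adjusted p = 0.00339). Its mean in hot leaves was 0.0837 CPM, below the floor of 3 reads, and with the log2 of CPM plus 1 it was at -0.67 and its call was lost.

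Members of these lists also passed at 6 h of heat. Antioxidant enzymes had 3 rises and 2 falls (3 and 3 adjusted over the list alone, camera adjusted p = 0.892). A monodehydroascorbate reductase (LOC_Os08g44340) fell from 38 to 9.52 CPM (adjusted p = 0.00196), and a chloroplast superoxide dismutase (LOC_Os06g02500) rose by 1.51 ± 0.45, a call lost without any single library of the 8 other than warm 6 h replicates 2 and 3. Chaperonins and DnaJ co-chaperones had 4 rises and 5 falls (the same adjusted over the list alone, camera adjusted p = 0.823). LOC_Os06g09679 rose by 1.68 ± 0.53, a call lost with no trend and no robust estimation and without any single library other than warm 6 h replicate 4. Respiratory chain complexes had 1 rise and 2 falls (the same adjusted over the list alone, camera adjusted p = 0.99). A hinge protein of ubiquinol-cytochrome C reductase (LOC_Os02g33730) rose by 0.88 ± 0.25, a call lost without any single library other than warm 6 h replicate 2 and hot 6 h replicate 3. NDA1 (LOC_Os01g61410) was at -0.77 ± 0.23, the 1 fall of the alternative pathway list (1 adjusted over the list alone, camera adjusted p = 0.075). Its call was lost with libraries shifted to one median, the log2 of CPM plus 1, no trend and no robust estimation, voom weights, and without any single library other than replicate 4 of either group.

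Of the proteasome subunits 1 rose at 6 h (1 rise and 1 fall adjusted over the list alone, camera adjusted p = 0.728), LOC_Os03g55110 by 0.73 ± 0.21, lost without warm 6 h replicates 1 or 4 or hot 6 h replicates 2, 3 or 4. In ribosome biogenesis it was the nucleolar protein NOP5 (LOC_Os03g44010, 0.65 ± 0.17, lost without hot 6 h replicate 2), with 1 adjusted over the list alone and camera adjusted p = 0.0848. Among splicing factors it was LOC_Os02g07420 (0.86 ± 0.27, 0 adjusted over the list alone, camera adjusted p = 0.854), lost with the replicate block, voom weights, and without any single library other than warm 6 h replicate 1 and hot 6 h replicate 2. A histone H3 (LOC_Os01g64640) of the dividing cell markers was at -2.05 ± 0.63. Its call was lost with the log2 of CPM plus 1 (-1.13), no trend and no robust estimation, only the groups compared, voom weights, and without any single library other than warm 6 h replicate 4 and hot 6 h replicate 3. With lane as a term each gene named for these lists at 6 h lost its call.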

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

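The tests on heat shock genes, on hot 24 h replicate 1 and on the size of changes with lane as a term were chosen after the result was seen, and the other tests in this part beforehand.

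Heat shock genes were mostly not called after the move to hot: HSP101 was at 0.42 at 2 h and the small heat shock protein list at a median of -0.389, while at 6 h HSP101 was at 0.64 (95% interval 0.02 to 1.25), HSP18.6 rose by 2.53 and the HSP70, HSP90 and HSP101 list had a median of 0.365 (camera adjusted p = 0.0223, and adjusted p = 0.649 with an estimated correlation). Swapped labels with the cold group are argued against by the cold leaves, where the small heat shock protein list had a median of -0.625 at 2 h. A swap with the warm group would put leaves labelled hot nearer to the cold ones than leaves labelled warm, but at 2 h 2907 genes differed between hot and cold (1664 without hot 2 h replicate 4, the lowest) against 0 to 1 between cold and warm, which argues against it although the heat stress transcription factors lay at a median of -0.705 in hot leaves. Too few reads or too wide a spread are argued against for HSP101, since the upper end of its 95% interval at 2 h was 1.04 on the log2 scale. The 5 small heat shock protein identifiers of the list that were not analysed here stay open, and a peak before 2 h was not sampled.

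No gene passed limma at 24 h of heat (1206 at an unadjusted p under 0.05, 0 with voom weights), and the count was 0 without hot 24 h replicate 1 and 3 without hot 24 h replicate 2. The genes changed at 2 h kept a fraction of 0.077 of their 6 h size at 24 h (-0.088 to 0.263 with single 24 h libraries left out). For these genes, that argues against a lasting response of the 6 h size hidden by the spread between the 24 h libraries. A smaller lasting response stays open. So does one in genes that changed first at 6 h or later, since these were not followed to 24 h as a set. That leaves may have returned to the warm state by 24 h is a hypothesis: 161 genes differed between 24 h and 2 h, a difference that contains the 2 h change (31 without warm 24 h replicate 2, 711 without hot 24 h replicate 2, with other libraries in the report), and 7 of 100 splits of the libraries gave as many (highest other 1405). These splits mix hours, so they do not decide whether chance gives that number.

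Sequencing lane runs with temperature in the heat comparisons. Within lane 2, genes called between lanes 1 and 3 kept a fraction of 0.585 of their change at 2 h and 0.693 at 6 h, and 93.8% to 98.1% of them at 2 h and 93.3% to 96.4% at 6 h had the same direction, which argues against lane as the whole cause. Each range covers 2 pairs that share 1 library, the warm one at 2 h and the hot one at 6 h. In the direction of the call, hot lane 3 minus hot lane 2 had a median of 0.574 at 2 h and 0.156 at 6 h. Warm lane 2 minus warm lane 1 had -0.005 and 0.239. With lane as a term 553 genes passed at 2 h and 267 at 6 h, yet the genes called without it kept a median share of 1.002 and 0.923 of their change, at standard errors 1.22 and 1.25 times as large, so the lost calls do not speak for lane. Lane as a part of the effect stays open, since the fractions within lane 2 lie below 1 and genes picked by their change shrink in other libraries without any lane effect too. Temperature itself, which the design varied, remains among the open explanations.

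Of 206 groups of 4 values tested for a library far from the rest, 8 had one, where chance gives about 1 in 20 or 10.3. In log2 CPM, the early light-induced protein LOC_Os07g08150 was at 1.52 in hot 6 h replicate 1 against 2.05 to 2.08 in its mates. LUX (LOC_Os01g74020) was at -3.42 in hot 2 h replicate 3 against -0.71 to -0.18. HSFA2C (LOC_Os10g28340) was at 6.32 in hot 6 h replicate 2 against 4.43 to 4.58. The transporter LOC_Os01g36720 was at 1.67 in warm 6 h replicate 4 against 3.07 to 3.27. The chaperonin-list gene LOC_Os06g09679 was at 2.35 in warm 6 h replicate 1 against 3.65 to 3.92. The mean correlation with group mates was 0.8597 for warm 0 h replicate 1 against 0.9223 to 0.9286, and 0.9638 for hot 6 h replicate 1 against 0.9588 to 0.9595. In warm 2 h replicate 1 the 10 most abundant genes took 11.31% of reads against 14.1% to 14.58%.

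The change at 24 h of heat differed from that at 2 h, in a test of the difference, for 161 genes in all. Among named genes the differences were -2.35 for LOC_Os01g12280 (adjusted p = 0.0455), 6.61 for LOC_Os06g48200, 6.57 for NCED4 (LOC_Os07g05940), -1.27 for PDIL2-3 (LOC_Os09g27830), 3.76 for GOLS1 (LOC_Os03g20120) and 1.24 for LOC_Os01g15860 (adjusted p = 0.0207).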

How the results depend on the processing

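The fits without warm 0 h replicate 1, without hot 24 h replicate 1 and without both were chosen after these libraries were seen, and the other tests beforehand. No called value of a named gene changed sign in any alternative; of 57 that passed, 32 did not pass with lane as a term, 46 with block and lane together, 9 with voom weights and 139 of 472 when single libraries were left out, and the filters, sample weights and added fits lost 0. Sign changes were counted as reversals only where a value passed on either side. The causes of the differences below were not tested, apart from the stricter threshold, which can only lower a count.

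Genes changed were 1584 at 2 h of heat, 1333 at 6 h, 564 for warm 24 h against 0 h and 161 for the hot difference between 24 h and 2 h. In that order, sample weights gave 3885 and 3887 for the heat hours and 1008 for the difference; fits of only the groups compared gave 2639, 2793, 1 and 47. Lane as a term gave 553, 267 and, for the difference, 374. Block and lane together gave 209, 192, 341 and 454. An adjusted p under 0.01 gave 462, 524, 55 and 18. The warm 24 h count was 337 with quantile normalization and 217 with voom weights. Without both doubted libraries the first 3 counts were 2705, 2110 and 110, and without warm 0 h replicate 1 the difference was 321. The replicate block alone gave 1613, 1345, 536 and 164. At 24 h of heat, where limma called 0 (1206 at an unadjusted p under 0.05), sample weights gave 8, lane 1 and block and lane 3. In the cold (0 in limma at each hour; 1251, 869 and 1457 at an unadjusted p under 0.05), quantile normalization gave 1 at 2 h (LOC_Os03g08580), log2 of CPM plus 1 gave 3 and 2 at 2 h and 6 h, voom weights 4 and 2, sample weights 4, 73 and 136, the filter at 3 gave 1 at 6 h (LHY), and the added fits 1 each at 2 h and 6 h, without warm 0 h replicate 1 and without both. The cold difference was 2 with sample weights. Genes opposite in heat and cold were 2 at 2 h with log2 of CPM plus 1 and 2 with voom weights; at 6 h they were 5 with sample weights and 1 with the filter at 3, log2 of CPM plus 1, voom weights and the 2 added fits. Of 150 list tests, 43 had a camera call, 0 with an estimated correlation, 13 with fry, 26 with lane and 41 with the block. The warm time course stayed within 1.5 times of 8626 in every alternative.

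Without single libraries of the groups compared the counts ran from 582 (hot 2 h replicate 4) to 1690 at 2 h of heat, with 910, 866 and 849 without warm 2 h replicates 1, 3 and 4 and 1008 and 762 without hot 2 h replicates 1 and 3; from 658 (warm 6 h replicate 1) to 1131 at 6 h, with 788 and 846 without hot 6 h replicates 2 and 4; from 0 to 3 (hot 24 h replicate 2) at 24 h; from 0 to 0, 0 to 1 (warm 6 h replicates 1 and 4) and 0 to 1 (warm 24 h replicate 2) in the cold; from 42 (warm 0 h replicate 1) to 1507 (replicate 2) for warm 24 h against 0 h, with 903 and 900 without warm 0 h replicates 3 and 4 and 130, 161 and 233 without warm 24 h replicates 1, 3 and 4; from 31 (warm 24 h replicate 2) to 711 (hot 24 h replicate 2) for the hot difference, with 86, 103 and 69 without warm 2 h replicates 1, 3 and 4, 78 without warm 24 h replicate 1, 282, 79 and 33 without hot 2 h replicates 2, 3 and 4, and 90 without hot 24 h replicate 1; from 0 to 0 for the cold difference; from 7660 to 8925 for the time course; and from 0 to 1 (warm 6 h replicate 1) for the opposite genes at 6 h. Of the splits of the same libraries, the real one included, 1 of 35 reached 1584 (highest other 29), 1 of 35 reached 1333 (10), 1 of 35 reached 564 (299) and 1 of 100 reached 8626 (6172). That argues against chance for these counts, although 1 of 35 is the lowest share possible there. For 564 the argument is weak. The count was 42 without warm 0 h replicate 1 and 1 when only these groups were fitted, both below the 299 of another split. For the hot difference (7 of 100, highest other 1405) and the cold difference (100 of 100, 1545) the splits mix hours and carry the day's structure, so they decide nothing there. Any split reaches a count of 0, so the splits decide nothing for the other counts. These were reached by 35 of 35 at 24 h of heat (highest other 81) and at 2, 6 and 24 h of cold (8, 1 and 2), and by 100 of 100 for the opposite genes (0). Without libraries of other groups the cold count was 1 at 2 h (warm 0 h replicates 1 and 4) and 1 at 6 h (warm 0 h replicate 1, hot 24 h replicates 2 and 4, cold 24 h replicate 1). Depth limits weak genes: 3 reads stood for up to 2.059 CPM.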

Other observations

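The test of opposite movement and the 4 added lists were chosen after the result was seen, and the tests on the day's course beforehand. The added lists include 34 nuclear-type light harvesting and photosystem genes. Another holds 104 genes of a kind normally found in the chloroplast genome but listed at nuclear loci, plastid ribosomal proteins among them. The nuclear-type genes had 2 rises and 1 fall at 6 h (5 and 1 adjusted over the list alone, median 0.648, camera adjusted p = 0.000288, and adjusted p = 0.658 with an estimated correlation). The chloroplast-type genes had 1 rise and 0 falls (0 and 0 adjusted over the list alone, median 0.365, camera adjusted p = 5e-05, and adjusted p = 0.62 with an estimated correlation), and reads of chloroplast transcripts can align to such loci. At 24 h of cold the medians were -0.501 and -0.284 (0 members by either adjustment, and adjusted p = 0.442 and 0.462 with an estimated correlation). At 2 h of cold the nuclear-type genes were at -0.107. The chloroplast-type genes were at 0.352 (0 rises over all genes, 2 adjusted over the list alone, camera adjusted p = 3.89e-06, and adjusted p = 0.781 with an estimated correlation). The 7 mitochondrion-type genes at nuclear loci had a median of 0.244 at 6 h of heat (0 members by either adjustment, and adjusted p = 0.62 with an estimated correlation). Their median at 2 h of cold was 0.269 (0 rises over all genes, 2 adjusted over the list alone, camera adjusted p = 0.0018, and adjusted p = 0.685 with an estimated correlation).

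Of 57 WRKY transcription factor genes, a family of stress and defence regulators, 2 fell at 2 h of heat (0 adjusted over the list alone), WRKY39 (LOC_Os02g16540) at -1.11 and WRKY5 (LOC_Os05g04640) at -1.11. At 6 h 1 rose (1 adjusted over the list alone), WRKY4 (LOC_Os03g55164) by 1.25 (camera adjusted p = 0.642 and 0.639). Of the flavonoid and phenylpropanoid genes, a dihydroflavonol-4-reductase (LOC_Os03g08624) rose by 2.91 and a flavonol synthase or flavanone 3-hydroxylase (LOC_Os10g40934) by 2.46 at 2 h of heat. Both calls were lost with lane as a term and without warm 2 h replicates 1 or 4 or hot 2 h replicates 3 or 4, and the former also without warm 2 h replicate 3 or hot 2 h replicate 1, with the log2 of CPM plus 1 and with voom weights. The latter was also lost with only the groups compared. LOC_Os03g08624 had a mean of 0.147 CPM in warm leaves, below the floor of 3 reads, so the size of its change depends on the offset (1.00 with the log2 of CPM plus 1).

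Heat and cold may move the same genes in opposite directions early on. With the 4 warm libraries split 2 and 2 between the comparisons, a share of 64.6% to 79.4% of the genes called in the heat at 2 h had the opposite sign in the cold over the 6 splits, against a mean of 53.2% of other genes. At 6 h the lowest share was 28.5% and the mean 49.4%, so the hypothesis was left open there.

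Heat could also set leaves further along the day's course. Across the 8626 genes that changed over the warm hours, the slope of the 2 h heat change on the warm change from 2 h to 6 h was 0.2 on average (0.16 to 0.243 over the 6 splits of the warm 2 h libraries), which is in line with that hypothesis. The 8626 genes were picked with all warm libraries, the split ones included. The splits therefore do not make the heat change and the warm change fully independent. LHY, which declines by day, was lower in hot leaves, the direction of the hypothesis. PRR1, FKF1 and LUX were lower too at 2 h, which goes against it for these genes. In warm leaves they rose between 2 h and 6 h, from 6.63 to 7.59, from 6.4 to 8.45 and from 0.79 to 7.06 log2 CPM. For the cold change the slope was 0.029 (-0.005 to 0.076), which leaves open whether cold leaves lag.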
